A study of Mus musculus with 20 samples.

How the data were processed

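RNA from mouse retina was measured on 20 Affymetrix gene arrays, each hybridised with biotinylated cRNA made with the manufacturer's 2-cycle labelling protocol. Per the labels, 4 cell layers were cut out by laser capture microdissection (photoreceptor layer, inner nuclear layer, inner plexiform layer and ganglion cell layer), and the whole retina was measured beside them. The C57BL/6 mice were adult and were either light adapted for 6 h or dark adapted for 3 h. The recorded illumination was 450 lux for light and 0.4 lux for dark adaptation. Each of the 10 combinations of tissue and adaptation has 2 arrays. The labels do not tie arrays to animals and do not give the number of animals behind an array, so every p-value measures the spread between deposited samples, which may be technical.

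The authors processed the arrays with GCRMA, a method that corrects for background and probe sequence, normalises between arrays and summarises probe sets; its version is not given. The deposited values are intensities on a linear scale, 1 per probe set and array, for 35557 probe sets. That the scale is linear was read from the values, since the labels do not state it: the median per array was 37.5 to 40.8 and the highest value per array was 3035.8 to 4713.1. The analysis plan, made before the data were examined, had assumed log2 values and set a rule for linear ones, which was followed: values under 8 were set to 8 and log2 was taken. Between 11.3% and 14.1% of the values of an array lay under this floor. The number of arrays limits the precision.

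The platform table gave exactly 1 gene symbol for 21789 probe sets, several symbols for 1621, and did not list 12147. A probe set was kept when at least 2 of the 20 arrays had a log2 value over 5, which left 16444 probe sets with 1 symbol. Each gene was represented by its probe set with the highest mean, giving 15057 genes. Genes without such a probe set are not reported here. No positions are printed, because the genome build of the probe table is not stated; a RefSeq gene table (GRCm38.p6) was used only to find which genes lie next to each other.

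All comparisons came from 1 limma fit (limma 3.58.1 in R 4.3.3) with a mean for each of the 10 groups, 10 residual degrees of freedom and moderated tests with an intensity trend. Tests were two-sided, with Benjamini-Hochberg adjustment within each comparison over all genes and a threshold of 0.05. Each layer was compared with the mean of the other 3 layers (4 arrays against 12) and with each other layer in turn, and the whole retina with the mean of the 4 layers (4 arrays against 16). Dark and light adaptation were compared within each of the 5 tissues (2 arrays against 2) and averaged over them (10 against 10), and a moderated F test asked whether the dark effect differed between tissues. Differences are on the log2 scale with the standard error of the fit; levels are given with the standard deviation.

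Before the data were examined, 25 gene lists were fixed: rod and cone phototransduction, photoreceptor structure and transcription factors, photoreceptor and ribbon synapse, primary cilium, visual cycle, markers of bipolar, amacrine, horizontal, Müller glia, ganglion, astrocyte, vascular, microglial and pigment epithelium cells, crystallins, circadian clock, immediate early genes, melatonin and dopamine signalling, oxidative phosphorylation, glycolysis, heat shock and unfolded protein response, retinal injury response, postsynaptic and dendritic genes, and cytosolic ribosomal proteins. Some genes stand in more than 1 list. List members were counted at the threshold over all genes and again adjusted over the list alone, and each list was tested with camera (preset correlation 0.01, and again with an estimated correlation), adjusted over the lists. Where both are given, the first p is that with the preset correlation.

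Genes are named by a rule fixed at the same time: the 10 with the largest positive and the 10 with the largest negative differences among called genes whose arrays do not overlap between the sides; up to 4 members, by smallest p, of each list that passed camera; the 5 smallest p where fewer than 5 genes passed in a direction; and fixed cell type and light-response markers. Genes that stand in the counts of layer-specific genes were picked from those by size of the smallest difference, after their values were seen.

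The alternatives tried were quantile normalisation, median centring, no filter and a filter at a log2 value of 7, the mean of a gene's probe sets, no intensity trend, array weights, a minimum log2 difference of 1, only the arrays of a comparison, the replicate number as a block, and leaving out each array in turn. Alternatives added after seeing the data were the Y-linked signal of an array as a covariate, the fit without 5 arrays with that signal, the signal of chemosensory receptor probe sets as a covariate, the fit without the light-adapted inner plexiform layer arrays, log2 of the intensity plus 16, the mean of the rod list as a covariate, and the list tests with each array left out in turn. The arrays with Y-linked signal include both light-adapted ganglion cell layer arrays. Without them, the layer and whole retina comparisons take that layer from its dark-adapted arrays alone, so adaptation and layer are mixed. The same holds for the inner plexiform layer in the fit without its light-adapted arrays. A planned comparison of 3' and 5' control probe sets was not run, because no such probe sets could be told apart by name.

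The fit was tested on simulated data with 200 of 15057 genes changed. Each gene was drawn on its own around its mean over all arrays, with its spread within groups. The simulation held no other tissue differences, no floor and no structure by replicate number, so it does not test the fit under those. In the photoreceptor layer comparison 167 of 200 genes changed by 1 log2 unit were found, with 8 false calls. For dark against light in the photoreceptor layer 45 of 200 were found at 1 log2 unit and 188 at 2, and in the average over tissues 187 at 1. The F test found 130 of 200 genes changed by 2 in a single group. In a simulated test of 25 lists of uncorrelated genes, camera called the 1 raised list and 0 of the others. This does not test the preset correlation on correlated genes.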

Results

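Transcript levels of 15057 genes were measured in 5 tissues of the mouse retina: the photoreceptor layer, the inner nuclear layer, the inner plexiform layer, the ganglion cell layer and the whole retina. Each tissue has 2 arrays from light-adapted and 2 from dark-adapted mice. Signal was even between arrays, with median intensities of 37.5 to 40.8, and the correlation between the replicates of a group, across genes, was 0.851 to 0.956. The first principal component held 46.6% of the variance. The light-adapted inner plexiform layer arrays had lower correlations with the other groups (medians of 0.738 and 0.768) than the other dissected arrays. So did replicate 2 of the light-adapted whole retina (0.721) and both dark-adapted whole retina arrays (0.783 and 0.770). Y-linked probe sets gave a median intensity of 357.1 to 493.65 in 5 of the 10 light-adapted arrays and of 7 to 11.4 in the 10 dark-adapted ones. Xist was at 23.2 to 29.2 in 4 of these 5 arrays. The single-copy Y gene Eif2s3y was at 94.7 in the whole retina array, at 19.3 in the photoreceptor layer array and at 7.8 to 9.7 in the other 3, against 3.4 to 6.8 in all arrays without that signal. The differences below, each with its standard error, compare the cell layers first and dark with light adaptation after that. The counts come from the fit without a block, and several were larger with the replicate number as a fixed block.

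The comparison of the photoreceptor layer with the other 3 layers asks which transcripts mark the cells that capture light. All 19 measured genes of the rod phototransduction list were higher there, with a median difference of 2.49 (camera adjusted p = 1.4e-35, and 0.0085 with an estimated correlation). Cnga1, a subunit of the rod cyclic nucleotide-gated channel, was 4.47 ± 0.50 higher (adjusted p = 1e-05, n = 4 against 12), and Rcvrn, which encodes recoverin, 3.49 ± 0.22. Rod transducin Gnat1 was higher by 2.83 ± 0.32 and the phosphodiesterase subunit Pde6a by 3.34 ± 0.34. In the cone list 8 of 10 genes were higher, among them cone arrestin Arr3 (3.27 ± 0.24), Pde6c (3.14 ± 0.18) and the medium-wavelength opsin Opn1mw (2.46 ± 0.20). The short-wavelength opsin Opn1sw was 3.09 ± 0.15 higher, a mean over 2 light-adapted arrays with strong signal and 2 dark-adapted arrays under the floor. The photoreceptor structure and transcription factor list had 14 of 15 genes higher (15 when adjusted over the list alone), including the interphotoreceptor matrix gene Impg1 (2.95 ± 0.18) and the disc rim gene Rom1 (2.75 ± 0.17). Outside these lists H2bc4, a histone gene, was higher by 3.80 ± 0.32, the apoptosis inhibitor Xiap by 3.44 ± 0.31, and the palmitoyltransferase gene Zdhhc2 by 3.18 ± 0.21. Rbp3, which carries retinoids between photoreceptors and pigment epithelium, was higher by 3.46 ± 0.38.

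Other groups were raised in the same layer by smaller amounts. The ribbon synapse list had 10 of 15 genes higher and 1 lower (median 0.86, estimated-correlation p = 0.040), led by complexin Cplx4 (3.04 ± 0.18) and the vesicular glutamate transporter Slc17a7 (1.96 ± 0.19). The primary cilium list had 11 of 19 higher and 14 when adjusted over the list alone (median 0.94, estimated-correlation p = 0.014), among them Bbs9 (2.09 ± 0.15), Arl3 (1.85 ± 0.17) and Cep290 (2.11 ± 0.22). Oxidative phosphorylation genes were higher in 5 of 17 cases, or 11 adjusted over the list alone (median 0.51, estimated-correlation p = 0.028), as with Ndufa4 (1.27 ± 0.18). In glycolysis 8 of 17 genes were higher and 1 lower (camera adjusted p = 0.0006, but 0.18 with an estimated correlation). Hexokinase Hk2 was higher by 2.40 ± 0.19 and the monocarboxylate transporter Slc16a1 by 1.83 ± 0.27, while Pfkm had a difference of -0.61 ± 0.13. The visual cycle list had 4 of 10 genes higher and 1 lower (p = 0.0060, and 0.081 with an estimated correlation), with Rdh12 at 1.96 ± 0.16. Markers of inner retinal cells were lower in the photoreceptor layer. Of the ganglion cell markers 13 of 19 were lower (median -0.71, estimated-correlation p = 0.025), as were 9 of 12 Müller glia markers (median -0.73, adjusted p = 7.5e-09, and 0.059 with an estimated correlation). Lower counts were 6 of 13 for bipolar and 5 of 11 for amacrine cell markers, both lists losing their call with an estimated correlation (adjusted p = 0.087 and 0.081). The neural transcription factor Pax6 was at -2.12 ± 0.22, glutamine synthetase Glul at -1.73 ± 0.25, the sodium pump subunit Atp1b1 at -2.23 ± 0.27 and the long noncoding RNA Meg3 at -2.03 ± 0.22. In all, 1093 genes were higher and 856 lower, and 460 were higher than in each other layer taken singly. Without the 5 arrays with Y-linked signal, a fit with fewer arrays, 1020 genes passed, and without each of the 4 photoreceptor arrays 1009 to 1207. The 460 were 252 without the former and 268 without replicate 2 of the light-adapted photoreceptor arrays.

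**Figure D1:**
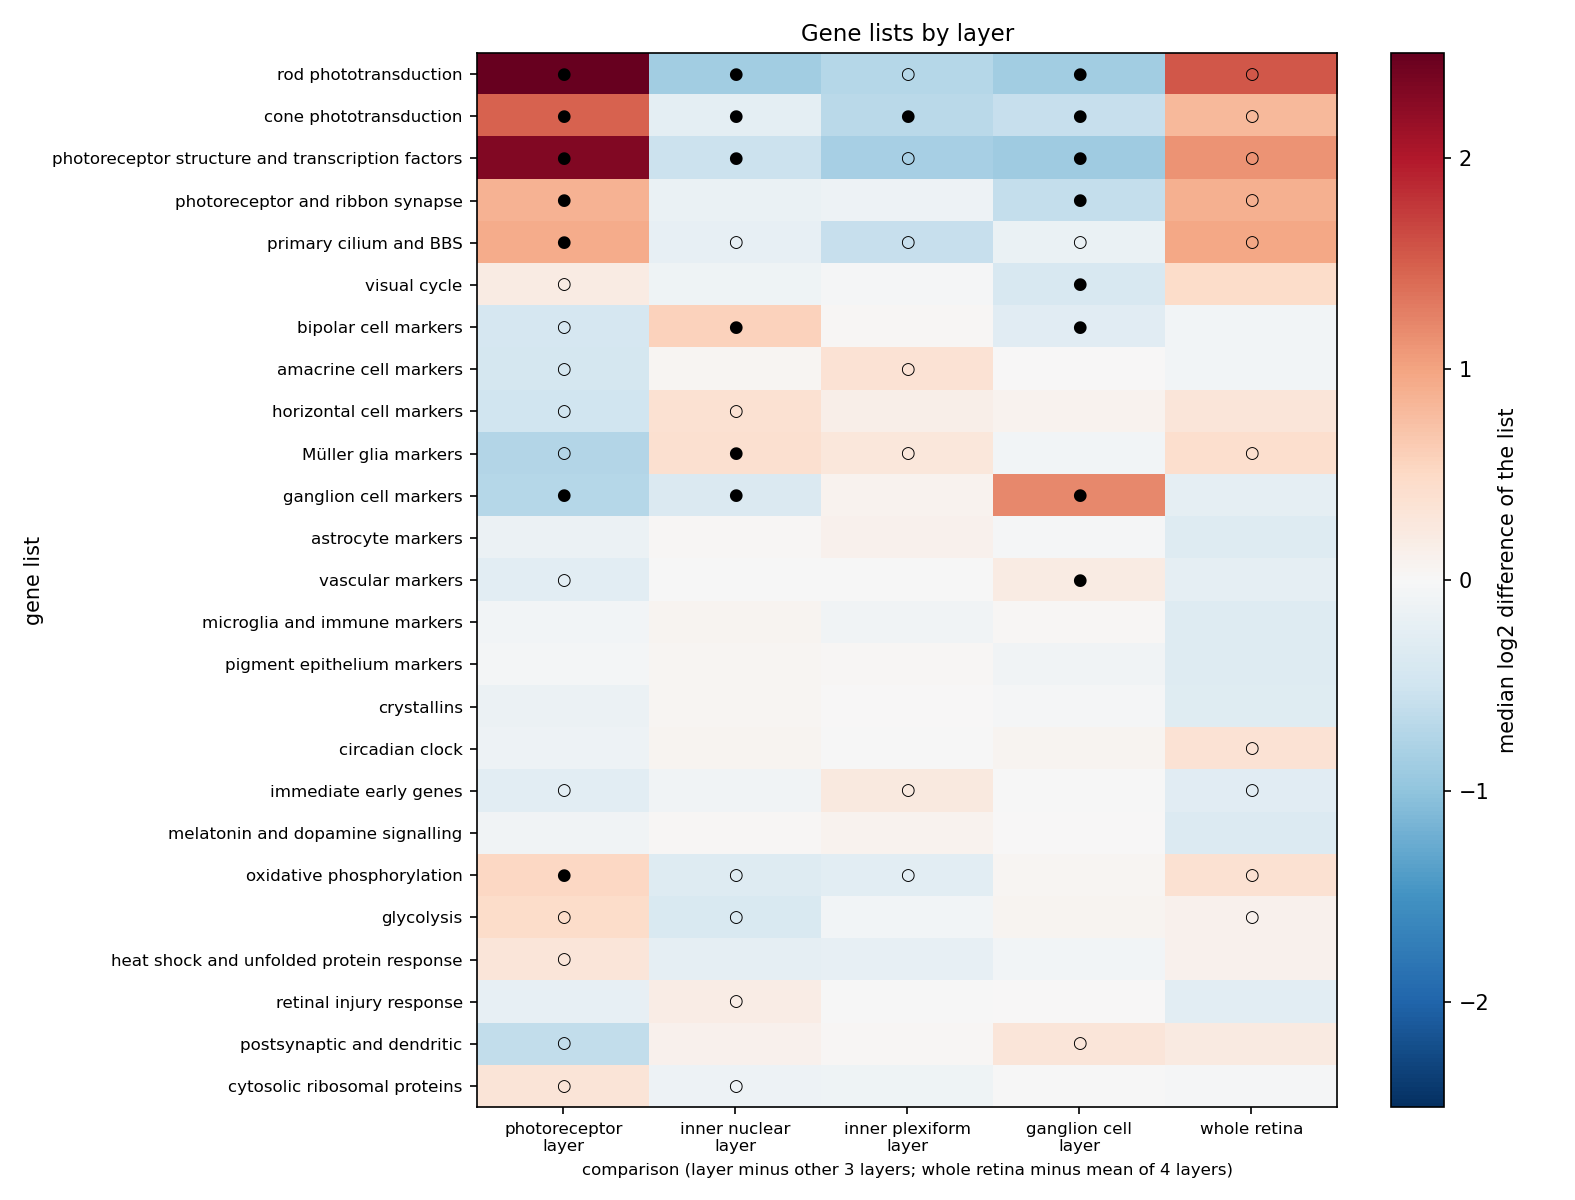
Median log2 difference (colour) of each of the 25 gene lists (vertical axis) in the 4 layers against the other 3 and in the whole retina against the mean of the layers (horizontal axis). Open circles mark lists past the threshold with the preset correlation, filled circles those that pass with an estimated correlation too. The rod list runs from 2.49 in the photoreceptor layer to -0.88 in the inner nuclear layer. For each inner layer, the other 3 layers include the photoreceptor layer.

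The inner nuclear layer holds the cell bodies of bipolar, horizontal, amacrine and Müller cells, and markers of the first and the last were higher there. Trpm1, the cation channel of ON bipolar cells, was higher by 1.54 ± 0.15 (adjusted p = 4.7e-05, n = 4 against 12). Other bipolar genes were higher too: the calcium-binding protein Cabp5 by 1.37 ± 0.27, the rod bipolar kinase Prkca by 1.06 ± 0.21 and Pcp2 by 0.76 ± 0.12. In all 5 of 13 bipolar markers were higher, and 9 when adjusted over the list alone (median 0.57, estimated-correlation p = 0.0085). Of the Müller glia markers 2 of 12 were higher, the retinaldehyde-binding protein gene Rlbp1 (1.38 ± 0.13) and Abca8a (1.34 ± 0.27); adjusted over the list alone there were 6 (median 0.39, estimated-correlation p = 0.047). Horizontal cell markers had a median of 0.38 with 0 of 6 called (p = 0.039, a call that 8 of 16 arrays each ended when left out, and 0.090 with an estimated correlation; the median was 0.15 without replicate 2 of the dark-adapted arrays), and Prox1 was at 1.32 ± 0.31 (adjusted p = 0.073). Amacrine cell markers gave no call as a group in this layer. Their mean level was 6.17 ± 0.08 (SD, n = 4), against 6.43 ± 0.34 in the inner plexiform, 6.33 ± 0.20 in the ganglion cell and 5.68 ± 0.11 in the photoreceptor layer. Outside the lists the GABA receptor subunit Gabrr3 was higher by 1.04 ± 0.18 and the cadherin Cdh8 by 0.95 ± 0.16. Photoreceptor lists were lower than the mean of the other 3 layers, which holds the photoreceptor layer. The rod list had a median of -0.88 with 4 of 19 genes called, 17 adjusted over the list alone (estimated-correlation p = 0.026), including Rcvrn at -1.48 ± 0.22 and Slc24a1 at -0.99 ± 0.13. Its mean level, 6.75, was near those of the inner plexiform (6.86) and ganglion cell (6.73) layers. Of the ganglion cell markers 2 of 19 were lower, Thy1 (-2.30 ± 0.13, with all 4 arrays under the floor) and Sncg (-0.90 ± 0.18). The microtubule gene Map1b was lower too (-1.50 ± 0.18). The ganglion cell list's mean level was 5.40, above the 5.235 of the photoreceptor layer and below the 6.93 of the ganglion cell layer. Glycolysis genes were lower in 3 of 17 cases (median -0.38, p = 9.5e-09, and 0.069 with an estimated correlation), with neuronal enolase Eno2 at -0.75 ± 0.16.

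The whole comparison gave 38 higher and 54 lower genes in the inner nuclear layer. Both this total and the next count were larger with the replicate number as a fixed block. Higher than in each other layer were 9 genes: Scgn, Trpm1, Samsn1, Rskr, Gabrr3, Rlbp1, Cdh8, Kcna5 and Lamp5. These 9 were 0 without the arrays with Y-linked signal, 0 without the light-adapted inner plexiform layer arrays, and 2 without replicate 2 of the light-adapted arrays of the layer or of the dark-adapted ganglion cell layer. The medians of the bipolar and Müller lists were 0.32 and 0.18 without replicate 2 of the dark-adapted arrays, both past the threshold. Of 100 groupings of the arrays 6 had as many as 92, the real one included, but the 5 others put all 4 photoreceptor layer arrays or 2 to 3 inner plexiform layer arrays under this layer's name and so hold those layers' differences. The 92 were 4 without the arrays with Y-linked signal, 47 without the light-adapted inner plexiform layer arrays, 56 with only the arrays of the 4 layers, 40 with no filter on dim probe sets, 60 without the intensity trend and 150 with the receptor signal as a covariate; leaving out replicate 1 or 2 gave 26 or 15 for the light-adapted and 61 or 53 for the dark-adapted arrays of the layer, and 61 or 47 and 50 or 54 for those of the photoreceptor layer.

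The inner plexiform layer, where bipolar, amacrine and ganglion cells form synapses, had 1248 genes higher and 797 lower. Amacrine cell markers were higher in 3 of 11 cases, 5 adjusted over the list alone: the transcription factors Tfap2a (0.88 ± 0.16) and Tfap2b (0.89 ± 0.20) and the GABA-synthesising enzyme Gad1 (0.55 ± 0.14, n = 4 against 12). The list's median was 0.36 (p = 0.011, but 0.20 without replicate 2 of the dark-adapted arrays, and 0.53 with an estimated correlation). Grm6, the glutamate receptor of ON bipolar dendrites, was higher by 0.99 ± 0.14. Immediate early genes were higher in 6 of 21 cases (median 0.24, p = 0.019, 0.069 without replicate 2 of the light-adapted arrays, and 0.53 with an estimated correlation), with Klf4 at 1.36 ± 0.20, Jund at 0.74 ± 0.13, Fosl2 at 0.75 ± 0.15 and Egr3 at 0.71 ± 0.15. Müller glia markers had 2 of 12 higher, Clu (0.72 ± 0.18) and Car14 (0.56 ± 0.13), with p = 0.025, a call that 4 of 16 arrays each ended when left out, and 0.68 with an estimated correlation. Cone genes were lower in 6 of 10 cases (median -0.67, estimated-correlation p = 0.012), as Arr3 (-1.55 ± 0.24) and Gnat2 (-1.14 ± 0.11). The rod list was lower in 9 of 19 cases (median -0.72, p = 7.6e-08, and 0.40 with an estimated correlation) and the cilium list in 8 of 19 (median -0.58, p = 1.3e-06, and 0.22). The other 3 layers hold the photoreceptor layer. The rod list's mean level here (6.86) was not below those of the inner nuclear (6.75) and ganglion cell (6.73) layers. Outside the lists, large differences included those of the microRNA gene Mir331 (1.87 ± 0.21), the odorant receptors Olfr603 (1.79 ± 0.26) and Olfr170 (-1.52 ± 0.14), and Rrad (1.30 ± 0.14). Gpatch8 (1.40 ± 0.14) shared its direction with 1 of its 4 other probe sets.

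In number these calls rested mainly on the light-adapted arrays. Within the light-adapted arrays 2367 genes passed, within the dark-adapted ones 9, and without the light-adapted inner plexiform layer arrays the comparison gave 35 genes. Without replicate 1 of the dark-adapted arrays it gave 1065, and without replicate 1 of the light-adapted ones 1319. Of the 2045 genes, 1992 had the same sign in the dark-adapted arrays. Their median absolute difference was 0.43 there, against 0.87 in the light-adapted arrays. The dark-adapted arrays helped to pick the 2045 genes, so the shared sign is no independent check. Of the named genes, Klf4 and Jund had larger differences in light, and Tfap2a, Gad1, Clu and Car14 in dark, a contrast that was not tested. Tfap2a was at 0.68 ± 0.23 in light and 1.08 ± 0.23 in dark, Gad1 at 0.38 ± 0.20 and 0.73 ± 0.20, Clu at 0.38 ± 0.26 and 1.06 ± 0.26, Car14 at 0.19 ± 0.18 and 0.93 ± 0.18, Klf4 at 1.80 ± 0.28 and 0.92 ± 0.28, and Jund at 1.19 ± 0.19 and 0.29 ± 0.19. The 176 genes higher than in each other layer fell in number to 1 without the light-adapted arrays of the layer, to 4 without the arrays with Y-linked signal, and to 23 without replicate 2 of the dark-adapted ganglion cell layer. Of 406 chemosensory receptor genes 16 were higher and 28 lower in this layer, 10.8% called against 13.7% of other genes. In the photoreceptor layer comparison these shares were 2.46% and 13.2%. Of 9260 probe sets outside the gene tests 1121 were higher and 1244 lower, against 203 and 212 in the photoreceptor layer. Background may thus account for part of these calls, which was not tested.

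The ganglion cell layer was set apart by genes of projection neurons. Thy1, a surface protein of ganglion cells, was at least 57.5-fold higher than in the other 3 layers (5.85 ± 0.13, adjusted p = 4e-15, n = 4 against 12, with 9 of the 12 under the floor). The neurofilament genes Nefl and Nefm were higher by 3.10 ± 0.37 and 2.66 ± 0.27, the vesicular glutamate transporter Slc17a6 by 2.29 ± 0.29, neuritin Nrn1 by 2.14 ± 0.19 and gamma-synuclein Sncg by 1.74 ± 0.18. In all, 13 of 19 ganglion cell markers were higher, 16 adjusted over the list alone (median 1.20, estimated-correlation p = 0.00049). Other large differences were those of calretinin Calb2 (2.89 ± 0.31), Sparcl1 (2.69 ± 0.21), the sodium pump subunit Atp1b1 (2.53 ± 0.27) and the G-protein regulator Rgs4 (1.95 ± 0.18). Vascular markers had 1 of 12 genes called, the pericyte gene Rgs5 (1.22 ± 0.21), and 3 adjusted over the list alone (median 0.21, estimated-correlation p = 0.032). The ribbon synapse list was lower in 8 of 15 cases (median -0.60, estimated-correlation p = 0.025), with Slc17a7 at -1.46 ± 0.19 and the calcium channel subunit Cacna2d4 at -0.99 ± 0.13. Rod genes were lower in 9 of 19 cases and bipolar markers in 3 of 13 (estimated-correlation p = 0.027 and 0.029), with Prkca at -1.03 ± 0.21 and Trpm1 at -0.79 ± 0.15. The rod list's mean level (6.73) was near those of the inner nuclear (6.75) and inner plexiform (6.86) layers. That of the bipolar list was 6.02 in this layer and 6.02 in the photoreceptor layer. The comparison gave 176 higher and 106 lower genes. Higher than in each other layer were 26 genes, among them the RNA-binding protein gene Rbpms, the kinesin Kif5a and the tachykinin Tac2. Fewer genes passed without the arrays with Y-linked signal, which include both light-adapted arrays of this layer. That fit takes the layer from its dark-adapted arrays alone, against light- and dark-adapted arrays of the others, so adaptation is mixed with layer. Without replicate 2 of the dark-adapted group 71 passed, without replicate 2 of the light-adapted group 183, and without replicate 2 of the light-adapted photoreceptor layer 180. The 26 were 2 without the arrays with Y-linked signal, 5 without the light-adapted inner plexiform layer arrays, 6 without replicate 2 of the dark-adapted group and 8 without replicate 2 of the light-adapted group. The rod list's median was -1.35 without the latter array and -0.57 without the other light-adapted one.

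Rod transcripts were also measured outside the photoreceptor layer. The mean log2 level of the 19 rod genes was 9.24 ± 0.06 (SD, n = 4) in the photoreceptor layer, 6.75 ± 0.63 in the inner nuclear, 6.86 ± 0.27 in the inner plexiform and 6.73 ± 0.67 in the ganglion cell layer, and 8.96 ± 0.08 in the whole retina. The lower rod lists of the inner layers above thus rest on the photoreceptor layer, which stands among the layers they were compared with. Between layers taken in pairs, 3218 genes differed between the photoreceptor and inner plexiform layers, 1154 between photoreceptor and ganglion cell layers, 802 between photoreceptor and inner nuclear layers, and 69 between the inner nuclear and ganglion cell layers.

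**Figure D2:**
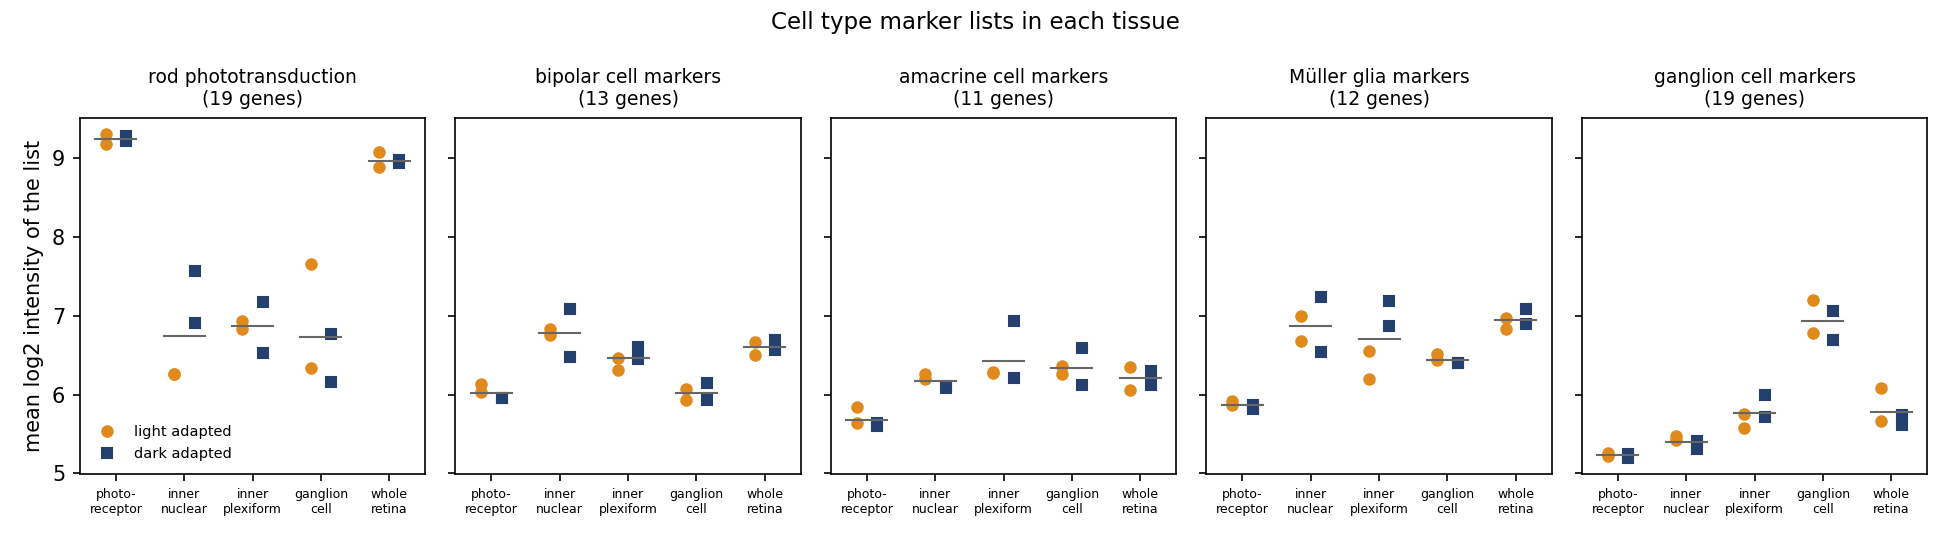
Mean log2 intensity (vertical axis) of 5 gene lists in each array of the 5 tissues (horizontal axis); circles are light-adapted and squares dark-adapted arrays, lines the mean of 4 arrays. The rod list stands at 9.24 in the photoreceptor layer and 8.96 in the whole retina, and between 6.73 and 6.86 in the other layers.

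The whole retina was compared with the mean of the 4 dissected layers as an undissected reference. Photoreceptor genes were higher in it, 17 of 19 rod genes (median 1.55) and 13 of 15 photoreceptor structure genes (median 1.12). So were 12 of 15 ribbon synapse genes (median 0.88) and 15 of 19 cilium genes (median 0.98). The cilium list's mean level was 7.09 ± 0.23 (SD, n = 4) in the whole retina, above that of every layer, with 6.73 ± 0.05 in the photoreceptor layer. With an estimated correlation the adjusted p-values of these 4 lists were 0.14, 0.13, 0.22 and 0.095. Examples are Pde6b (2.22 ± 0.26, n = 4 against 16), Rp1 (2.52 ± 0.30), Cplx4 (2.07 ± 0.18) and Bbs9 (1.94 ± 0.14). Müller glia markers were higher in 6 of 12 cases, with Rlbp1 at 1.16 ± 0.13 (list p = 0.0091, and 0.48 with an estimated correlation). Clock genes were higher in 8 of 17 cases, as Clock itself (1.39 ± 0.27) and Rorb (1.28 ± 0.22), with list p = 0.037, a call that 3 of 20 arrays each ended when left out, and 0.48 with an estimated correlation. The rod bipolar kinase Prkca was higher by 1.49 ± 0.20. The largest differences were those of Rbm12b2 (3.20 ± 0.45), Zfp654 (3.11 ± 0.23), Zdhhc17 (3.10 ± 0.30), the ciliary gene Cep290 (2.80 ± 0.22), the noncoding RNA Tug1 (2.78 ± 0.30), the nuclear exporter Xpo1 (2.73 ± 0.36) and topoisomerase Top2b (2.70 ± 0.29). Immediate early genes were lower in 9 of 21 cases, as Klf4 (-1.34 ± 0.19), Jund (-0.81 ± 0.13), Egr4 (-1.10 ± 0.19) and Fos (-0.83 ± 0.16), with list p = 0.0091, and 0.37 with an estimated correlation; the list's median was -0.28, and -0.45 without replicate 1 of the light-adapted whole retina. The endothelial gene Plvap was at -1.40 ± 0.16 and neurogranin Nrgn at -1.26 ± 0.15.

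In this comparison 2991 genes were higher and 4310 lower, and the median of all genes was -0.18 (-0.16 after quantile normalisation and -0.13 after median centring). Without replicate 2 of the light-adapted whole retina 3884 genes passed. Of 406 tested odorant, vomeronasal and other chemosensory receptor genes, 145 were lower and 11 higher, with a median of -0.37; with the receptor signal of an array as a covariate 10 of 15057 genes passed, and Clock turned to -0.30 ± 0.37. That signal is itself lower in the whole retina (3.34, against 3.67 to 3.75 in the layers), so the covariate takes out the tissue difference too and cannot tell it from background.

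Dark against light adaptation was compared in each tissue. In the photoreceptor layer the short-wavelength cone opsin Opn1sw was at 628 and 556.7 intensity units in the light-adapted arrays and at 1.4 and 1.5 in the dark-adapted ones, at least 73.9-fold lower in the dark (-6.21 ± 0.26, adjusted p = 2e-10, n = 2 against 2). The other 9 cone genes had a median difference of 0.07, from -0.21 to 0.84, and 0 of them passed in limma; Gnat1 was at 0.04 ± 0.55 and arrestin Sag at -0.30 ± 0.47. Higher in the dark were 6 genes: Paip2, a repressor of translation (2.23 ± 0.22), the transcriptional repressor Zhx2 (2.14 ± 0.35), the sodium pump subunit Atp1b3 (1.96 ± 0.26), neuroligin Nlgn2 (1.67 ± 0.22), the glutamate transporter Slc1a1 (1.59 ± 0.24) and the sulfotransferase Chst10 (1.59 ± 0.25). The dopamine receptor Drd4 was at 0.51 ± 0.22, Fos at -0.10 ± 0.28 and Per1 at -0.13 ± 0.25, none past the threshold, and 224 genes had an unadjusted p under 0.05. Leaving out single arrays of the layer left 2 or 3 of the 7 calls in number, and leaving out the arrays with Y-linked signal 2, Opn1sw (-6.12 ± 0.39) and Paip2 (2.28 ± 0.24). The other 5 kept their direction there with fewer arrays and larger standard errors: Nlgn2 at 1.87 ± 0.29, Atp1b3 at 1.87 ± 0.30, Zhx2 at 1.79 ± 0.39, Slc1a1 at 1.57 ± 0.31 and Chst10 at 1.57 ± 0.29.

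In the whole retina Opn1sw was at 594.1 and 600.8 in light and 4.5 and 2.9 in dark, at least 74.7-fold lower (-6.22 ± 0.26, adjusted p = 1.9e-10, n = 2 against 2). Zhx2 (2.26 ± 0.35), Slc1a1 (2.02 ± 0.24) and Atp1b3 (1.61 ± 0.26) were higher. These 4 genes were all among the 7 of the photoreceptor layer, in the same direction, where 0.0019 would be expected of independent calls (Fisher's exact p = 1.6e-14). The calls share 1 fit and its spread per gene, so they are not independent and this p does not decide. Across all genes the Spearman correlation was 0.029. With the inner plexiform layer, the photoreceptor layer shared 3 genes, 1 in the same direction (Fisher's exact p = 0.0002), and the whole retina 2, with 0 in the same direction (0.0020). The other 3 genes of the photoreceptor layer did not pass in the whole retina: Paip2 was at 1.05 ± 0.22, Nlgn2 at 0.10 ± 0.22 and Chst10 at -0.15 ± 0.25. Without the arrays with Y-linked signal Opn1sw alone passed (-6.23 ± 0.39), with Zhx2 at 2.68 ± 0.39, Slc1a1 at 1.96 ± 0.31 and Atp1b3 at 1.64 ± 0.30; 1 gene also passed when only the whole retina arrays were used.

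In the inner plexiform layer 108 genes were higher and 168 lower in the dark. Müller glia markers had 2 of 12 genes higher, Rlbp1 (1.40 ± 0.23, adjusted p = 0.011, n = 2 against 2) and the potassium channel Kcnj10 (1.11 ± 0.26); adjusted over the list alone 5 were higher and 1 lower (median 0.66, adjusted p = 0.00069, and 0.87 with an estimated correlation). Without replicate 1 of the light-adapted arrays the median was 0.40 and the list did not pass (adjusted p = 0.11). The glutamate transporter Slc1a1 was lower, from 289.9 and 301.2 to 19.9 and 37 intensity units (-3.44 ± 0.24, adjusted p = 7.4e-07), the opposite of its direction in the photoreceptor layer and the whole retina. The small RNA gene Rny1 was at -3.12 ± 0.35. Higher were Npn2 (3.19 ± 0.51), the secretory granule gene Scg3 (2.07 ± 0.37), the neuronal GTPase Rit2 (2.20 ± 0.39), the protease cathepsin L, Ctsl (2.22 ± 0.41), and Bex1 (2.33 ± 0.48, a lower bound since both light-adapted arrays lay under the floor). These standard errors take the spread over all 10 groups. Between the 2 dark-adapted arrays of the layer, the SD of these higher genes ran from 0.39 log2 units for Scg3 to 1.25 for Ctsl. Hmcn1 (2.22 ± 0.53) shared its direction with 17 of its 43 other probe sets. With array weights 3 genes passed, and with only the layer's own arrays 4. More genes passed with the replicate number as a fixed block and with the receptor signal as a covariate. The number fell without some single arrays and rose without others.

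The inner nuclear layer had 0 genes past the threshold in limma and 473 with an unadjusted p under 0.05; the smallest adjusted p was 0.12, for Syne2 (1.62 ± 0.26, n = 2 against 2). Rod genes stood higher there in the dark as a group (median 0.70, camera adjusted p = 2.4e-17, and 0.25 with an estimated correlation), with 7 of 19 higher when adjusted over the list alone and a median of 0.43 without replicate 2 of the dark-adapted arrays and 1.11 without replicate 1; Gnat1 was at 2.21 ± 0.55 and Slc24a1 at 1.02 ± 0.23. The photoreceptor structure list was higher too (median 0.54, p = 5.6e-09, and 0.27 with an estimated correlation), while the cone list had a median of 0.00065 (p = 0.94). The ribbon synapse and cilium lists passed (medians 0.18 and 0.11, p = 0.00097 and 0.0083, and 0.57 for both with an estimated correlation) but not without replicate 2 of the dark-adapted arrays, where their medians were -0.09 and 0.02, nor without replicate 1 of the light-adapted ones; without replicate 1 of the dark-adapted arrays the medians were 0.53 and 0.44. In the ganglion cell layer the rod list had a median of -0.48 (p = 5.7e-05, and 0.85 with an estimated correlation). This rested mainly on 1 array: the rod mean of replicate 2 of the light-adapted arrays was 7.66, against 6.33 in replicate 1 and 6.76 and 6.16 in the dark, and without it the median was -0.0077, and -1.03 without replicate 1. The vomeronasal receptor Vmn1r74 (-2.31 ± 0.34, adjusted p = 0.045) was the 1 gene past the threshold in that layer, with 614 at an unadjusted p under 0.05. Array weights, the Y-linked, receptor or rod signal as a covariate and a random block by adaptation and replicate number each ended this call. So did the layer's own arrays alone, the filter at a log2 value of 7 and leaving out any of the layer's 4 arrays.

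Averaged over the 5 tissues, Paip2 was higher in the dark (0.91 ± 0.10, adjusted p = 0.0004, n = 10 against 10) and Opn1sw lower (-2.48 ± 0.11). Neither difference was common to all tissues. Paip2 was at -0.95 in the inner nuclear layer. Opn1sw was at -6.21 in the photoreceptor layer and -6.22 in the whole retina, and near or under the floor elsewhere. Immediate early genes were lower as a group, with 0 of 21 called (median -0.10, p = 0.0056, a call that 2 of 20 arrays each ended when left out, and 0.89 with an estimated correlation); Dusp1 was at -0.42 ± 0.11, Egr1 at -0.51 ± 0.17 and Fos at -0.29 ± 0.12. Müller glia markers stood higher with 0 of 12 called (median 0.14, p = 0.042, a call that 9 of 20 arrays each ended when left out, and 0.93 with an estimated correlation); the median was 0.03 and 0.22 without replicates 2 and 1 of the dark-adapted inner nuclear layer, and -0.06 with the Y-linked signal as a covariate. Clock genes had a median of 0.03 and 0 of 17 called in limma, with Per1 at -0.15 ± 0.11, Per2 at 0.08 ± 0.11 and Dbp at -0.05 ± 0.13. Melatonin and dopamine genes had a median of 0.07 and 0 of 9 called, 1 of them higher adjusted over the list alone. At an unadjusted p under 0.05 there were 920 genes. The total of 2 was not beyond regrouping, as 8 of 100 regroupings of the arrays within tissues gave as many. Parting the same arrays by replicate number in all tissues gave 960. The regroupings took no account of that number, and with it as a fixed block more than 2 genes passed.

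The dark effect differed between tissues for 4 genes by the moderated F test. With the filter at a log2 value of 7 the number was 2, and Opn1sw and Atp1b3 had adjusted p = 0.23. It was 7 with array weights, 8 with no filter and 10 with the receptor signal as a covariate. The number was larger still with the replicate number as a fixed block, and it rose without some single arrays. Opn1sw (adjusted p = 2.1e-09) was lower in the dark in the photoreceptor layer and the whole retina and lay near or under the floor in the other layers. Slc1a1 (4.7e-07) was at 1.59 in the photoreceptor layer, 2.02 in the whole retina, 0.54 in the ganglion cell layer and -3.44 in the inner plexiform layer. Atp1b3 (0.00021) was at 1.96 and 1.61 in the photoreceptor layer and whole retina, and at -1.56 and -1.18 in the inner nuclear and inner plexiform layers, where all 4 dark-adapted arrays lay under the floor. Paip2 (0.0013) was at 2.23 in the photoreceptor layer and 0.98 in the inner plexiform layer, and at 1.25, 1.05 and -0.95 in the ganglion cell layer, whole retina and inner nuclear layer, where it did not pass.

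**Figure D3:**
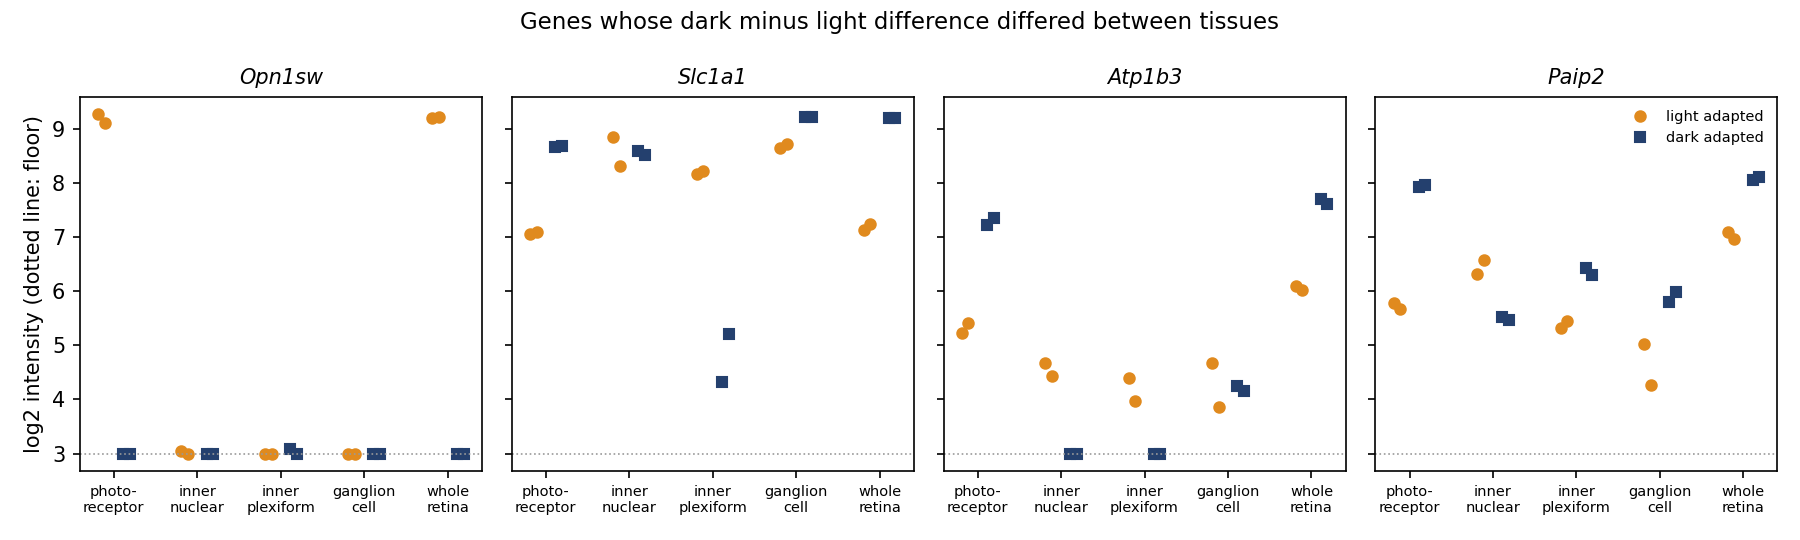
Log2 intensity (vertical axis) of 4 genes in each array of the 5 tissues (horizontal axis); circles are light-adapted and squares dark-adapted arrays, and the dotted line is the floor. Opn1sw has signal in the light-adapted photoreceptor layer and whole retina arrays and lies at the floor in their dark-adapted ones, while Slc1a1 is higher in the dark there and lower in the inner plexiform layer (-3.44).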

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

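The tests of cone content, sex and genotype below were chosen after the results were seen. So were those of the receptor genes, lost cells and rod share in the whole retina. The same holds for sex and rod carry-over in the inner plexiform layer, the make-up of the splits and the split by replicate number. Predictions for the neighbours of Opn1sw, the receptor genes in the inner plexiform layer and the regrouped arrays were written before those tests were run. The Opn1sw and inner plexiform layer patterns that they address were themselves found in these data.

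The dark effect of 4 genes differed between tissues, by a test of the difference itself: Opn1sw (adjusted p = 2.07e-09), Slc1a1 (4.66e-07), Atp1b3 (0.00021) and Paip2 (0.00132). Fewer cones in the dark-adapted samples are argued against, since the other 9 cone genes had a median of 0.070 in the photoreceptor layer where Opn1sw was at -6.21, and so is sex, since Opn1sw was at -6.12 without the arrays with Y-linked signal. A deletion reaching the genes around Opn1sw is argued against by the 10 nearest tested genes, with a median of -0.20, though a change within Opn1sw alone is not tested by them. For the other genes a genotype difference between the dark- and light-adapted animals stays open: 3 of 3 went both ways between tissues by more than 2 standard errors, but they were picked for differing between tissues, so this decides nothing. The dark adaptation itself stays open, and so does the length of adaptation, recorded as 6 h for light and 3 h for dark. Any unrecorded difference between the light and dark arrays, such as the day of processing, stays open too. Each may account for the pattern.

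Signal in probe sets not used in the comparisons set 5 arrays apart: the median of 22 Y-linked probe sets that name several genes was 493.65, 473.2, 472.9, 361.15 and 357.1 in the light-adapted photoreceptor layer replicate 1, inner nuclear layer replicate 1, ganglion cell layer replicates 1 and 2 and whole retina replicate 1. The dark-adapted arrays lay between 7 and 11.4. Xist was at 23.2 to 29.2 in 4 of these arrays and at 240 in the light-adapted ganglion cell layer replicate 2, where both signals were present. The single-copy Y gene Eif2s3y was at 94.7, 19.3 and 7.8 to 9.7 in these arrays, against at most 6.8 in the others, so the Y-linked signal rests mainly on the multicopy probe sets.

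The whole retina differed from the mean of the layers in 7301 genes, 4310 of them lower. Cells lost in the dissection would raise their markers in the whole retina, so the medians of pigment epithelium, vascular and astrocyte markers, the highest -0.22, do not decide on genes lower in it. Background and amplification noise of the dissected samples may account for lower genes, as chemosensory receptor genes were lower too, with a median of -0.37. The rod list lay 84.9% of the way from the mean of the layers to the photoreceptor layer on the log2 scale, which is not a share of RNA. A larger share of photoreceptor RNA in the whole retina than in the mean of the layers is a candidate explanation for it. A mean of log2 levels over the layers also lies below the level of an equal mixture of them, so part of the rise may come from the scale. The cilium list stood at 7.09 ± 0.23 (SD, n = 4) in the whole retina, above its 5.61 to 6.73 in the layers. The clock list was at 6.78 ± 0.12, against 6.39 to 6.51. A larger share of photoreceptor RNA does not by itself account for levels above those of every layer. How many of the 7301 genes each explanation accounts for was not tested, and no biological explanation other than tissue was tested.

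In the inner plexiform layer 276 genes differed between dark and light. Male against female arrays are argued against, since the highest Y-linked signal of its 4 arrays was 41. A mixed share of sexes stays open, with Xist at 73 and 56.6 in the light-adapted arrays and 124.1 and 418.6 in the dark-adapted ones. Photoreceptor RNA carried into the layer is argued against too, since 237 of the 276 genes passed with the rod list as a covariate as well. Poor quality of the light-adapted arrays of the layer stays open and may account for part of the pattern: receptor genes passed the threshold in 2.22% of cases, as against 1.82% of the other genes. Probe sets outside the gene tests passed more often than genes, with 646 higher and 315 lower of 9260. The adaptation itself stays open as a biological explanation, and its length differed between light and dark.

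The layer results were set against chance regroupings of the same arrays, 100 splits each with the real one included. A split mixes arrays of several layers, which widens the spread within groups and lowers its count. It also takes no account of the replicate number. Few splits with as many genes therefore do not exclude chance for a single layer. For the photoreceptor layer 1 split gave as many as its 1949 genes (highest other 1189). For the inner plexiform layer it was 1 (2045, highest other 277) and for the ganglion cell layer 3 (282, highest other 480). Under the ganglion cell layer's name, the split with 480 genes held 3 inner plexiform layer arrays and that with 417 held 3 photoreceptor layer arrays. For the inner nuclear layer 6 splits gave as many as 92, and the highest other gave 1612. That split put the 4 photoreceptor layer arrays under the layer's name and the 4 next ones 2 to 3 inner plexiform layer arrays, so the structure they show is that of the other layers, and they do not decide on chance. For genes higher than in each other layer, 1 split gave as many as the 460 of the photoreceptor layer (highest other 4), 2 as many as the 9 of the inner nuclear layer (highest other 424, again with the photoreceptor layer arrays), 1 as many as the 176 of the inner plexiform layer (highest other 1), and 1 as many as the 26 of the ganglion cell layer (highest other 2). For the whole retina 1 split gave as many as 7301 (highest other 1511). For dark against light averaged over the tissues chance cannot be excluded: 8 splits gave as many as 2 genes, and the highest other gave 17. That split parted replicate 1 from replicate 2 the same way in 4 of the 5 tissues and the other way in 1, and the split by number in all 5 gave 960 genes, which points to a structure of the arrays by number, though the labels do not say what a number marks.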

How the results depend on the processing

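Across the alternatives other than leave-one-out fits, the named genes gave 453 weaker, 68 stronger and 4 reversed results, and 4420 that passed in the same direction. The cause of a move was not tested unless stated. With array weights the counts were 2942 for the photoreceptor layer, 1065 for the inner plexiform layer, 12, 1, 3 and 0 for dark against light in the photoreceptor, inner nuclear, inner plexiform and ganglion cell layers, 5, 30 and 17 for genes higher than in each other layer in the inner nuclear, inner plexiform and ganglion cell layers, and 7 for the difference of the dark effect. Asking for an absolute log2 difference of at least 1 can only lower counts, to 519, 30, 246 and 99 for the 4 layers in the order from photoreceptor to ganglion cell, 1355 for the whole retina, 1 for the averaged dark effect, and 261, 2 and 33 for genes higher than in each other layer in the photoreceptor, inner nuclear and inner plexiform layers. Without the 5 arrays with Y-linked signal, chosen after the result was seen, the 4 layers gave 1020, 4, 1287 and 48, the dark effect 2 in the photoreceptor layer, 82 in the inner plexiform layer and 1 in the whole retina, and genes higher than in each other layer 252, 0, 4 and 2. With Y-linked signal as a covariate, also chosen later, the dark effect gave 164 genes in the inner plexiform layer, 0 in the ganglion cell layer, 2 in the whole retina and 1 averaged, 5 genes were higher in the inner nuclear layer than in each other layer, and the Müller glia list's averaged median turned to -0.057. With no filter on dim probe sets there were 40 genes for the inner nuclear and 184 for the ganglion cell layer, 4 and 5 for the dark effect in the photoreceptor and ganglion cell layers, 4 and 12 higher than in each other layer for the inner nuclear and ganglion cell layers, and 8 for the difference of the dark effect. With the filter at a log2 value of 7 there were 1052 for the inner plexiform layer, 2745 for the whole retina, 0 for the dark effect in the ganglion cell layer, 1 in the whole retina, 1 averaged, 3 higher in the inner nuclear layer than in each other layer, and 2 for the difference of the dark effect. Without the intensity trend the inner nuclear layer gave 60, and after quantile normalization the dark effect in the inner plexiform layer gave 176. With the chemosensory receptor signal as a covariate, chosen later, there were 150 for the inner nuclear layer, 10 for the whole retina, 423 and 0 for the dark effect in the inner plexiform and ganglion cell layers, 115 higher in the inner plexiform layer than in each other layer, and 10 for the difference of the dark effect. This signal is lower in the whole retina than in the layers, so that fit takes out the tissue difference too. In it, for the whole retina, Clu turned to -0.027, Clock to -0.30, and the circadian clock, glycolysis and postsynaptic lists to medians of -0.21, -0.33 and -0.39. With the rod phototransduction list as a covariate, chosen later, the dark effect in the ganglion cell layer gave 0. Without the light-adapted inner plexiform layer arrays, chosen later, the inner nuclear layer gave 47 and the inner plexiform layer 35, and genes higher than in each other layer were 0, 1 and 5 in the inner nuclear, inner plexiform and ganglion cell layers. With only the arrays of the comparison there were 56 for the inner nuclear layer, 4, 0 and 1 for the dark effect in the inner plexiform layer, ganglion cell layer and whole retina, and 5 higher in the inner nuclear layer than in each other layer. With an estimated correlation camera called 22 list results where it called 69 with the preset one. With the mean of all probe sets of a gene Gpatch8 turned to 0.28 in the whole retina and Hmcn1 to -0.11 in the dark-adapted inner plexiform layer.

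Replicate numbers were checked for pairing by the correlation, between groups, of the difference of replicates 1 and 2. It was over 0.1 in 32 of 45 pairs of groups (median 0.13, from 0.0059 to 0.48). The numbers were not taken as paired, as not all pairs lay over 0.1 and the labels do not say what a number marks. This was a choice and does not show that the numbers are unrelated. Structure by number may thus stay in the spread of the main fit. As a hint from the data of such structure, all 45 correlations were above 0. The first principal component was higher in replicate 1 than in replicate 2 in each of the 10 groups. Parting the arrays by number in all tissues gave 960 genes. The replicate number as a fixed replicate block gave 239 for the inner nuclear and 510 for the ganglion cell layer, 781 for the dark effect in the inner plexiform layer, 7 averaged, 14, 343 and 56 for genes higher than in each other layer in the inner nuclear, inner plexiform and ganglion cell layers, and 27 for the difference of the dark effect. As a random replicate block by adaptation and number it gave 0 for the dark effect in the ganglion cell layer, 2 averaged, 290 higher in the inner plexiform layer than in each other layer, and 8 for the difference of the dark effect.

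Leave-one-out fits leave some groups with 1 array, which is assumed to vary like the others. Their counts ran from 1009 to 2200 for the photoreceptor layer, 15 to 128 for the inner nuclear, 1065 to 2381 for the inner plexiform and 71 to 351 for the ganglion cell layer, and 3884 to 7629 for the whole retina. The dark effect ran from 2 to 3 in the photoreceptor layer, 17 to 371 in the inner plexiform layer, 0 to 2 in the ganglion cell layer, 2 to 3 in the whole retina and 2 to 3 averaged. Genes higher than in each other layer ran from 268 to 490 in the photoreceptor, 2 to 16 in the inner nuclear, 23 to 214 in the inner plexiform and 6 to 39 in the ganglion cell layer, and the difference of the dark effect from 4 to 14. Of 69 list results past the threshold, 22 lost their call without 1 array or another, tested after the results were seen, and the sign of the median changed for 3: the ribbon synapse list in the dark-adapted inner nuclear layer, the photoreceptor structure list in the dark-adapted ganglion cell layer and glycolysis in the whole retina. The 3' to 5' ratio of control probes was not run.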

Other observations

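Some list results were not described above. In the photoreceptor layer ribosomal protein genes were higher in 5 of 15 cases (median 0.32, adjusted p = 0.0025, and 0.070 with an estimated correlation), led by Rpl8 (1.32 ± 0.18); the median was 0.17 without replicate 1 of the dark-adapted layer. The heat shock and unfolded protein list had 4 of 11 genes higher there (median 0.30, adjusted p = 0.020, and 0.11 with an estimated correlation), with the chaperone genes Hsp90aa1 at 1.54 ± 0.28 and Hspa1a at 0.73 ± 0.15. The postsynaptic and dendritic list had 5 of 13 genes lower and 1 higher (median -0.61, adjusted p = 0.0009, and 0.11 with an estimated correlation): the scaffold gene Dlgap1 was at -0.70 ± 0.15 and Map2, which stabilises dendritic microtubules, at 1.08 ± 0.25. Immediate early genes were lower in 5 of 21 cases, with Klf4 at -0.73 ± 0.20 (adjusted p = 0.033, a call that 4 of 16 arrays each ended when left out, and 0.30 with an estimated correlation). Horizontal cell markers were lower in 2 of 6 cases, as Onecut1 (-0.51 ± 0.14), and vascular markers in 1 of 12, Flt1 (-1.50 ± 0.17); their adjusted p-values were 0.020 (0.067 without replicate 2 of the light-adapted photoreceptor layer) and 0.035, and 0.070 and 0.081 with an estimated correlation.

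A further 7 lists gave no call as groups in the photoreceptor layer: astrocyte markers (median -0.15, adjusted p = 0.58), microglia and immune markers (-0.07, adjusted p = 0.83), crystallins (-0.15, adjusted p = 0.38), pigment epithelium markers (-0.05, adjusted p = 0.90), circadian clock genes (-0.13, adjusted p = 0.87), melatonin and dopamine genes (-0.09, adjusted p = 0.90) and the retinal injury response (-0.21, adjusted p = 0.14). Injury response genes stood higher in the inner nuclear layer with 0 of 11 called (median 0.19, adjusted p = 0.039, a call that 5 of 16 arrays each ended when left out, and 0.090 with an estimated correlation); the median was 0.07 and 0.31 without replicates 1 and 2 of the dark-adapted inner nuclear layer. In the whole retina 5 of 9 crystallin genes, 5 of 9 melatonin and dopamine genes and 4 of 9 pigment epithelium genes were lower, with list adjusted p-values of 0.12, 0.28 and 0.24.

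Probe sets that the gene tests left out, 7869 with no listed gene and 1391 with several, were tested by themselves. In the inner plexiform layer 646 of these 9260 were higher and 315 lower in the dark, against 2 and 1 in the photoreceptor layer and 1 and 0 in the whole retina. Among the 15057 genes 108 were higher and 168 lower in the inner plexiform layer, a smaller share with more genes lower than higher. The cause of this difference was not tested.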
